A study of Rattus norvegicus with 25 samples.

How the data were processed

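Liver RNA of individual male rats was measured on CodeLink UniSet Rat I arrays, 1 biotin-labelled sample per array, per the labels' protocols. The deposited scanner tables give, per the file headers, the intensity of each spot before and after subtraction of a local background, the background intensity and a flag of 0 or 1 (unit other), with no normalization between arrays. The flag marks spots that are missing in the deposited value table, so flagged spots were treated as defective, between 54 and 169 per array. The authors' value table holds a processed signal on a linear scale, with array medians of 0.716 to 0.972 and rank correlations of 0.997 to 0.9997 with the scanner values of the same array, so its direction is that of the scanner values. It holds 28 zeros, which were set to missing. How the authors normalized it, the scanner and its software are not given in the sources used here, and the table served as an alternative.

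Each array holds 10399 spots, of which 9911 are gene probes and 488 are controls. Background was corrected with limma's normexp (offset 50) on all spots, controls were removed, defective spots were set to missing, and gene probes were quantile normalized and taken to log2. The files give no detection flag, so a probe was tested if its value lay above the array median in at least 50% of the samples of 1 group. Above background means an intensity over the median plus 3 MADs of 7 kinds of bacterial control spots that sit at background on every array. The platform annotation, with symbols updated through gene identifiers in a RefSeq table (GRCr8, used for names only), or the probe's RNA accession, gave 7351 probes a single symbol. Another 91 had several and 2469 none, and those were tested but not named. A gene is represented by its brightest probe.

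Before the data were examined, 25 arrays were planned as 25 samples. Of 29 pairs of arrays of the same group and array set, 2 were nearly identical by limits chosen after seeing the values (spread under 0.15 and ratio of spreads under 1.25). Each such pair was averaged, leaving 23 samples. Array sets were found by single linkage on shared defective spots (overlap over 0.5), also after the data were seen. The labels say that RNA was not pooled, so each remaining sample was taken as 1 rat. Deviations of 36 same-numbered pairs of samples of different groups had a median correlation of -0.037, with 8 above 0.1 and the highest 0.693 for deficient 6 and chow 6, so the numbers were not used as pairs.

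Groups were compared with limma 3.58.1 in R 4.3.3, with all groups in 1 fit, least squares for each pattern of missing spots, empirical Bayes moderation and Benjamini-Hochberg adjustment over the probes of a comparison (threshold 0.05, 2-sided). The design gave 8 comparisons. A comparison of repletion with chow was added after seeing the data, because the repletion samples share an array set with part of the chow samples. The array set was added as a fixed block, as a random block and by testing within a set. Gene lists (24) and cell type marker lists (12) were fixed before the data were examined and tested with camera (preset correlation 0.01), with an estimated correlation, and with fry. With the array set as a block, camera was run with the preset correlation only. Of the 36 lists, 4 had fewer than 3 measured members and were not tested. Besides these tests, genes adjusted over the list alone were counted.

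Named genes followed a rule fixed beforehand. Up to 10 risen and 10 fallen genes of a comparison qualified by size of change if they passed the threshold, lay above background in every array of a group and had every sample of the first group on the same side of the other group's mean. Up to 4 members of each described list and 9 genes of redox and mitochondrial signalling were added, and the text gives a selection of those that qualified. Some genes that qualified are not reported here. Tools were tested on simulated data. With 200 changed probes among 5449 in the deficient against supplemented comparison, 46.4% of changes of 0.5 on the log2 scale, 88% of 1 and 98.8% of 2 were recovered, and 4.9% of calls were false. With simulated differences between array sets and no block 16% of calls were false, and with the block 5.2%. Alternatives tried were other background, normalization, filter, flag, weighting, threshold, group and covariate choices and leaving out each sample. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were also used.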

Results

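Liver RNA from individual male Sprague-Dawley rats was hybridized to 25 single-colour oligonucleotide arrays. By their labels, 6 arrays were of rats fed laboratory chow, 6 of rats fed a purified diet with the redox cofactor pyrroloquinoline quinone (PQQ, supplemented), 6 of rats fed the same basal diet without it (deficient), 3 of rats switched from the supplemented to the deficient diet for 48 h (depletion) and 4 of deficient rats injected with PQQ at 1.5 mg per kg every 12 h for 36 h (repletion). Each array carried 9911 gene probes, and the median probe intensity minus background ranged from 103.2 to 281 between arrays. Between 83.6% and 90.3% of the measured probes lay above background. The number of arrays limits the precision of every comparison.

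A pair of chow arrays (1 and 2) and a pair of supplemented arrays (5 and 6) were nearly identical. Their log2 ratios had spreads of 0.11 and 0.112, against 0.214 to 0.401 in the other same-group pairs. At genes that vary between rats their spread was 0.98 and 1.18 times that at steady genes, against 1.7 to 3.24 times in the other pairs. Each pair was averaged and counted as 1 sample, which left 5 chow and 5 supplemented samples. The arrays also fell into 5 sets that shared defective spots, with overlaps of 0.646 to 0.956 within sets and 0.142 to 0.327 between sets. Set 1 held chow 1 to 3 and supplemented 1, set 2 held supplemented 2 and 3, and set 3 held supplemented 4 to 6 and deficient 1 to 5. Set 4 held deficient 6 and the depletion samples, and set 5 held chow 4 to 6 and the repletion samples. Each comparison is therefore also described with the array set as a block.

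The comparison of deficient with supplemented rats asked what a diet without PQQ from late gestation onward changed in the liver. Genes of the circadian clock were among those that differed. Dbp, a clock output transcription factor, was 4.91-fold higher in deficient rats (log2 difference 2.30, SE 0.31, 6 deficient and 5 supplemented samples, limma adjusted p = 0.000309), and the clock repressors Cry2 and Nr1d2 were higher by 1.21 and 0.76. Bmal1, a core activator of the clock, was 2.73-fold lower (log2 difference -1.45, SE 0.22, adjusted p = 0.000714). Of 6 measured genes of the clock list, 3 rose, 1 fell and 2 did not pass, and 5 passed when adjusted over the list alone. The list as a whole was higher (camera adjusted p = 0.00755), although with an estimated correlation its adjusted p was 0.0521. With the array set as a block and the preset correlation its camera adjusted p was 0.0385. Under that block Dbp, Cry2, Nr1d2 and Bmal1 differed by 1.97, 1.07, 0.51 and -1.30 and none of them passed. Within array set 3, where the differences were the same, Dbp and Bmal1 passed (adjusted p = 0.00627 and 0.047) and Cry2 and Nr1d2 did not (0.0729 and 0.114).

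Genes of cholesterol synthesis and uptake were lower in deficient rats. The median log2 difference of 16 measured members was -0.52 (camera adjusted p = 3.02e-07, and adjusted p = 0.0489 with an estimated correlation). Of these, 3 fell, none rose and 13 did not pass, while 10 passed when adjusted over the list alone. Idi1, Mvd and Fdps, enzymes of the isoprenoid part of the pathway, fell by 0.85, 0.80 and 0.53 on the log2 scale (SE 0.19, 0.18 and 0.12). Cyp51, a sterol demethylase, was 2-fold lower without passing (adjusted p = 0.0761). Its value in deficient 6 was 10.09, against 11.99 to 12.23 in the other deficient samples. Under the block for array set Cyp51 was at -0.72 and did not pass. The block for array set gave the list a median of -0.57 (camera adjusted p = 2.95e-09 with the preset correlation), while Idi1, Mvd and Fdps were at -0.81, -1.01 and -0.40 and did not pass. The blocked difference rests on the 5 deficient and 2 supplemented samples of array set 3.

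**Figure D1:**
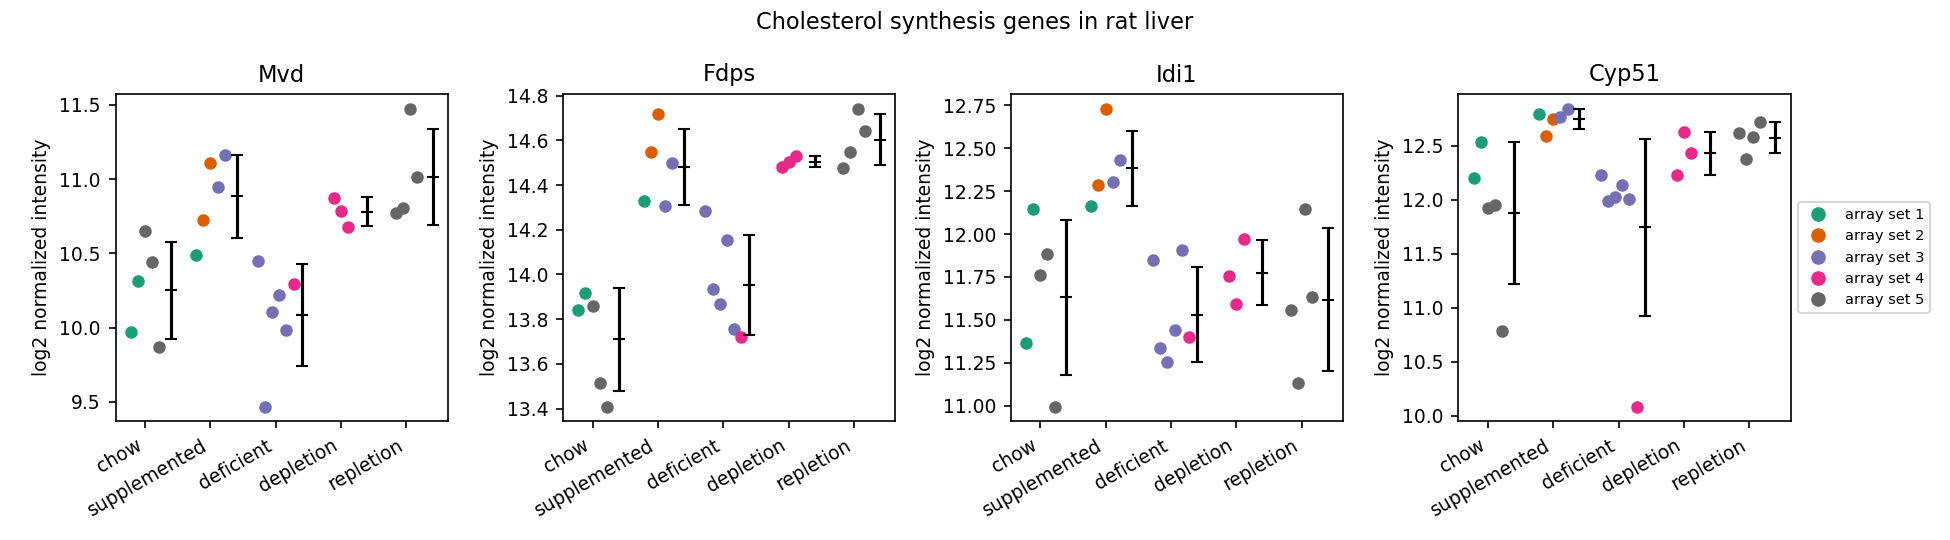
Log2 normalized intensity of Mvd, Fdps, Idi1 and Cyp51 in each sample by group, with points coloured by array set and bars for the mean and SD of the group. The deficient mean of Fdps was 13.95 and the supplemented mean 14.48, and the lowest Cyp51 value, 10.09, belonged to deficient 6.

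Marker genes of Kupffer cells, the resident macrophages of the liver, were lower in deficient rats (8 measured, median -0.26, camera adjusted p = 0.00278, and adjusted p = 0.245 with an estimated correlation). Cd14, a lipopolysaccharide co-receptor, fell by 0.76 and Lyz2, a lysozyme, by 1.06, the other 6 did not pass, and 2 passed when adjusted over the list alone. The proteasome list also lay lower, by a median of -0.14 over 29 genes (camera adjusted p = 0.00614, and adjusted p = 0.201 with an estimated correlation), and none of its members passed over all probes or over the list alone. Psmd1 and Psmd9 differed by -0.63 and -0.37 (adjusted p = 0.0851 and 0.12). Under the block the medians of the Kupffer and proteasome lists were -0.40 and -0.18 (camera adjusted p = 0.000226 for both with the preset correlation), and Cd14 (-0.72) and Lyz2 (-0.95) did not pass. The other 28 lists tested had camera adjusted p of 0.055 to 0.717.

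Other genes that were higher in deficient rats were Marveld1 (log2 difference 1.97, SE 0.46), Ppm1k, a phosphatase of branched-chain amino acid breakdown (1.52, SE 0.22), Bcar3 (0.93), Gne (0.88), Mcrip2 (0.84), Tp53i13 (0.82), Kiaa1191 (0.80) and Higd1a (0.79). Tsku (-2.58, SE 0.53), the cell cycle inhibitor Cdkn1a (-1.83, SE 0.41), Lpin1, a phosphatidate phosphatase (-1.70, SE 0.36), Pkdcc (-1.38), Med20 (-1.28) and Irf2bpl (-1.24) were lower. For As3mt and Ssr4 (-3.38 and -2.11) a single deficient sample was usable, so no difference between the groups is claimed. Of the genes examined in every comparison, Txnip, Txn1, Stat3 and Tfam differed by 0.39, -0.19, -0.20 and -0.06 and did not pass, and Txnrd1, Ppargc1a, Jak2 and Nrf1 were not measured past the filter. In all, 94 probes rose and 85 fell of 5449 tested, which corresponded to 63 and 59 genes. The block for array set gave 13 probes, 10 of them among the 179, and 4 of the 25 called genes named here, which were Marveld1 (2.74), Kiaa1191 (0.77), Tsku (-3.22) and Pkdcc (-1.41), although 176 of the 179 probes kept their sign, and within set 3, with 5 deficient and 2 supplemented samples, 9 passed. There Tsku and Cdkn1a passed (adjusted p = 0.00447 and 0.0494), whereas Marveld1, Kiaa1191 and Pkdcc did not (0.0729, 0.0949 and 0.0729). Leaving out supplemented 1 gave 82 probes.

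**Figure D2:**
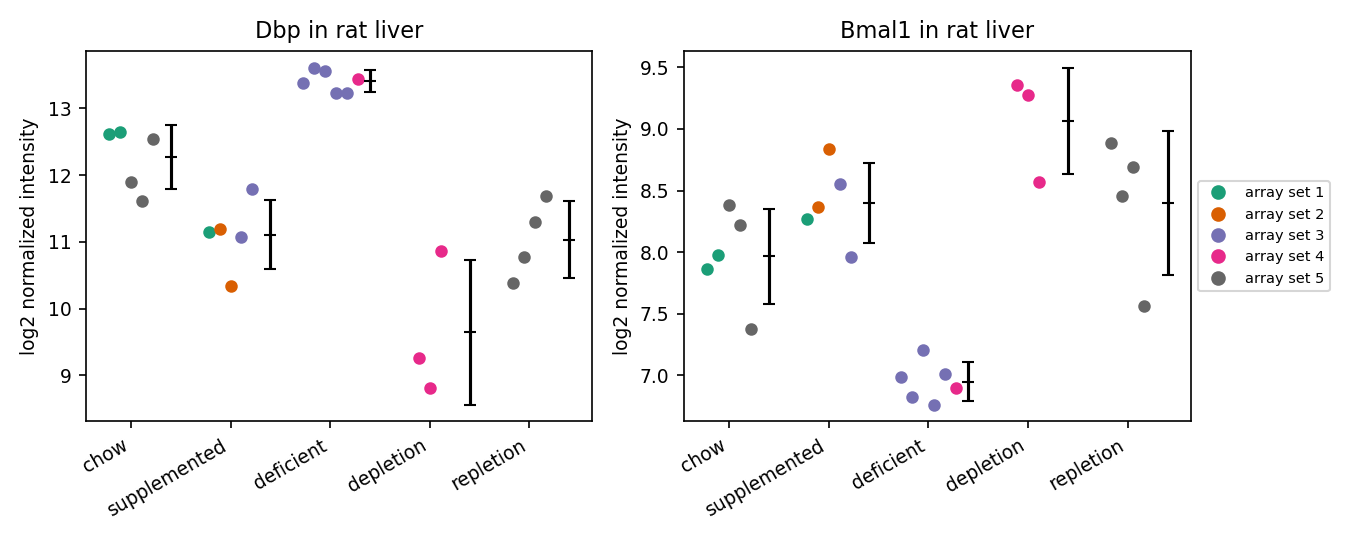
Log2 normalized intensity of Dbp and Bmal1 in each sample by group, with points coloured by array set and bars for the mean and SD of the group. The deficient samples had the highest mean of Dbp (13.40) and the lowest mean of Bmal1 (6.95).

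The comparison of repletion with deficient rats asked what PQQ injection changed after a diet without it, and the labels name no group injected with vehicle. Dbp was 5.17-fold lower after repletion (log2 difference -2.37, SE 0.33, 4 repletion and 6 deficient samples, adjusted p = 3.36e-05) and Bmal1 was 2.73-fold higher (1.45, SE 0.23), while Cry2 and Nr1d2 fell by 1.20 and 0.83. Hacl1, a peroxisomal lyase of fatty acid alpha-oxidation, was 4.03-fold lower (-2.01, SE 0.18, adjusted p = 3.83e-07). Ribosomal protein genes were higher, with 12 of 23 risen, 11 not passing and 15 passing when adjusted over the list alone (median 0.52, camera adjusted p = 0.000275, and adjusted p = 0.622 with an estimated correlation). Rps18, Rps20, Rpl21 and Rpsa rose by 0.82, 0.79, 0.50 and 1.01. Their median under the block for array set was 0.08 (camera adjusted p = 0.757).

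Genes of cholesterol synthesis were higher after repletion, with 6 of 15 risen, 9 not passing and 6 passing when adjusted over the list alone (median 0.38, camera adjusted p = 0.0255, and adjusted p = 0.622 with an estimated correlation). Fdps, Mvd, Insig2 and Hmgcs1 rose by 0.65, 0.93, 0.99 and 1.08. With the array set as a block the list's median was 0.51 (camera adjusted p = 0.00105), but Hmgcs1 turned to -0.28. In the oxidative phosphorylation list 8 of 26 genes rose, 1 fell and 17 did not pass, and 9 passed when adjusted over the list alone (median 0.36, camera adjusted p = 0.0194, and adjusted p = 0.622 with an estimated correlation). Cox4i1, Atp5f1d and Atp5mc2 rose by 1.17, 0.86 and 0.87, and Uqcrc2 fell by 0.68. With the block this list had a median of -0.04 (camera adjusted p = 0.9), and Cox4i1 and Atp5f1d turned to -0.24 and -0.04. The other 29 lists had camera adjusted p of 0.277 to 0.967.

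Among the largest rises after repletion were those of Kcnt1 (log2 difference 3.66, SE 0.72), Araf (3.52), Lman1 (2.67), Cdk11b (2.62) and Sppl2a (2.36). As3mt and Ssr4 (3.49 and 2.53) stood against that single deficient sample, and no change is claimed. Syt11, Scaf11, Cyp2c22, Ahctf1 and Ppm1k fell by 2.02, 1.88, 1.85, 1.84 and 1.69. Txn1, the cytosolic thioredoxin, rose by 0.41, and its inhibitor Txnip fell by 0.78, whereas Tfam (-0.11) and Stat3 (-0.03) did not pass. In all, 840 probes rose and 1129 fell of 5424 tested (594 and 769 genes), and 13 genes had called probes of opposite sign. With the array set as a block, repletion was tied to the deficient samples only through chow and, from chow, only through supplemented 1. Under it 63 probes passed, 61 higher and 2 lower and 6 of them among the 1969, and none of the genes named here did. The median SE rose from 0.151 to 0.31, and 1449 of the 1969 probes kept their sign. Bmal1 (1.35), Hacl1 (-1.55), Fdps (0.97), Mvd (1.36), Rpsa (1.02) and Dbp (-1.46) kept their direction, Kcnt1, Araf and Sppl2a shrank to 0.93, 0.79 and 0.16, and Syt11 and Txnip turned to 0.32 and 0.07. Txn1 shrank to 0.02, Lman1 to 0.83, Cdk11b to 0.16, Cyp2c22 to -0.28, Nr1d2 to -0.16 and Scaf11 to -0.01.

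**Figure D3:**
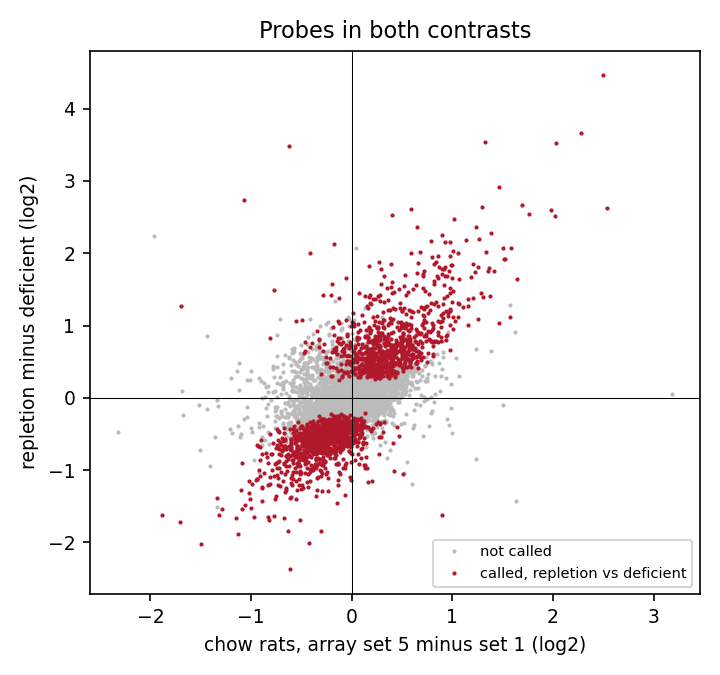
Log2 difference between repletion and deficient samples (vertical) against the log2 difference between chow samples of array sets 5 and 1 (horizontal), 1 point per probe, with red for probes called between repletion and deficient samples. The values correlated across probes (r = 0.609), and 89.5% of the called probes had the same sign in both, with no array shared between the axes.

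The comparison of depletion with supplemented rats asked what 48 h without dietary PQQ changed. Hacl1 was 2.56-fold lower (log2 difference -1.36, SE 0.20, 3 depletion and 5 supplemented samples, adjusted p = 0.00507), and Rarb, a retinoic acid receptor, was 2.55-fold higher (1.35, SE 0.25, adjusted p = 0.0188). Ddhd1, a phospholipase, and Ednra, an endothelin receptor, rose by 0.96 and 0.63. Rer1, Flt1, Ntrk3, Atad2 and Ncan fell by 0.94, 0.71, 0.70, 0.61 and 0.61, although Ntrk3 reversed to 0.767 with defective spots kept. Dbp and Usp2 differed by -1.46 and -1.12 and Bmal1 by 0.67, which did not pass (adjusted p = 0.0676, 0.116 and 0.219). Txnip, Txn1, Stat3 and Tfam differed by -0.21, 0.04, -0.36 and -0.01 and did not pass. None of the 32 lists passed (camera adjusted p of 0.195 to 0.861). In all, 4 probes rose and 6 fell, and 796 had an unadjusted p under 0.05. Of the 10 called probes, 6 were also called between repletion and deficient rats, in the same direction, among them Hacl1. Under the block for array set Hacl1 (-1.84), Rarb (1.98), Ddhd1 (1.10) and Ncan (-0.84) passed, whereas Ednra (0.05), Rer1 (-0.65), Flt1 (-0.41), Ntrk3 (-0.42) and Atad2 (-0.32) did not. Usp2 and Tfam, not called without the block, moved to -2.26 and 0.57 under it, but through deficient 6 alone, so no change is claimed. Scaling each array to a common median moved the median of all probes from 0.01 to 0.14 and called 195 rises and 57 falls (77.4% higher, against 40% here), and the authors' table gave 21 and 48. The array set as a random block left 0 probes and as a fixed block gave 1513, among them 5 of the 10, a count that rests on deficient 6, the only sample linking depletion to another set.

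Against supplemented rats, chow rats had 8.74-fold more Hsd17b6 mRNA, for a hydroxysteroid dehydrogenase (log2 difference 3.13, SE 0.48, 5 samples in each group, adjusted p = 0.000878), and more Cyp3a9 (1.99), Sds, a serine dehydratase (1.78), and Mgll, a monoacylglycerol lipase (1.74). Zfp354a, the protease inhibitor A2m and Lpin1 were lower (-2.08, -1.52 and -1.42). Cholesterol synthesis genes were lower in chow rats, with 7 of 16 fallen, 9 not passing and 11 passing when adjusted over the list alone (median -0.52, camera adjusted p = 0.00392, and adjusted p = 0.612 with an estimated correlation), among them Msmo1 (-1.42), Sqle (-1.17), Lss (-0.77) and Fdps (-0.77). Fatty acid synthesis genes were lower too, with 4 of 17 fallen, 13 not passing and 5 passing when adjusted over the list alone (median -0.46, camera adjusted p = 0.00396, and adjusted p = 0.612 with an estimated correlation), among them Fads1 (-0.94), Fads2 (-0.61) and Acsl3 (-0.65). Both lists under the block for array set had a camera adjusted p of 0.201, Acsl3 was at 0.01, and of the 14 called genes named here only Cyp3a9 (2.11) passed. Hsd17b6 (2.94), Zfp354a (-2.97), Lpin1 (-1.65), A2m (-1.32), Fads1 (-1.16) and Fads2 (-0.74) did not pass with differences of a similar size, and Sds and Mgll shrank to 0.90 and 0.77. The block tied chow to the supplemented group only through supplemented 1. In all, 271 probes rose and 246 fell, 121 passed with the block (103 higher and 18 lower, 28 of them among the 517) and 132 within set 1, where 2 chow samples stood against 1 supplemented sample. The authors' table gave 243 and 132 (64.8% higher, against 52.4% here), and leaving out chow 6 gave 209 probes.

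Against deficient rats, chow rats again had more Hsd17b6 (3.06, SE 0.46) and Mgll (2.04) and less A2m (-1.91), Syt11 (-2.04) and Mobp (-1.81). Kupffer cell markers were higher in chow rats, with 5 of 8 risen, 3 not passing and 6 passing when adjusted over the list alone (median 0.53, camera adjusted p = 0.00506, and adjusted p = 0.533 with an estimated correlation). Cd14, Lyz2, C1qa and Aif1 rose by 1.26, 0.92, 0.72 and 0.46, and with the array set as a block the list's camera adjusted p was 0.297. Txn1 rose by 0.49 and Bmal1 by 1.02. In all, 655 probes rose and 839 fell, and 91 passed with the block, 87 higher and 4 lower and 16 of them among the 1494, with none among the 11 called genes named here. Hsd17b6, Mgll, A2m, Syt11 and Mobp were then at 3.90, 1.41, -2.03, -0.29 and -0.82. The block tied chow to the deficient samples only through supplemented 1. Diet base and PQQ differed together in both comparisons with chow.

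Between repletion and supplemented rats, Kcnt1, Araf and Lman1 were higher after repletion (3.30, 3.22 and 2.08), and Cyp2c22, Hacl1 and Ahctf1 were lower (-1.95, -1.62 and -1.60). Oxidative phosphorylation genes were higher, with 6 of 26 risen, 1 fallen, 19 not passing and 8 passing when adjusted over the list alone (median 0.35, camera adjusted p = 0.00351, and adjusted p = 0.711 with an estimated correlation), among them Cox4i1 (0.96) and, in the other direction, Uqcrc2 (-0.52). Ribosomal protein genes were higher, with 5 of 23 risen, 18 not passing and 6 passing when adjusted over the list alone (median 0.27, camera adjusted p = 0.00263, and adjusted p = 0.765 with an estimated correlation), among them Rps18 (0.77) and Rps20 (0.65). Neither list passed under the block for array set (camera adjusted p = 0.81 and 0.901), and Cox4i1 turned to -0.34. The block tied repletion to the supplemented samples only through chow and supplemented 1. None of the 10 genes named here passed under it, and Kcnt1, Araf, Lman1 and Cyp2c22 shrank to 0.86, 0.71, 0.35 and -0.996, with Hacl1 and Ahctf1 at -1.29 and -1.41. In all, 466 probes rose and 572 fell, 71 passed with the block (69 higher and 2 lower, 6 of them among the 1038), and none did with array number as a covariate. Without the block, the differences correlated across probes at 0.655 with those between chow samples of array sets 5 and 1. The sign was the same in both for 93% of the called probes, so array set is a candidate cause.

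Between depletion and deficient rats, Dbp was 13.5-fold lower in depletion rats (log2 difference -3.76, SE 0.36, 3 depletion and 6 deficient samples, adjusted p = 3.68e-06), Usp2 and Nr1d2 fell by 1.99 and 1.06, and Bmal1 was 4.34-fold higher. Of 6 clock genes 4 fell, 1 rose and 1 did not pass, with 5 passing when adjusted over the list alone (camera adjusted p = 0.0033, and adjusted p = 0.0279 with an estimated correlation). Cdkn1a (2.25), Slc28a2 (1.76) and Rarb (1.50) were higher, and Hacl1 (-1.75), Pfkfb1 (-1.34) and Ptp4a1 (-1.28) were lower. Cholesterol synthesis (4 of 16 risen, 4 when adjusted over the list alone, Insig2 1.18 and Fdps 0.55), fatty acid synthesis (2 of 17, 3 over the list alone, Acsl3 0.68 and Agpat2 0.53) and proteasome genes (2 of 29, 2 over the list alone, Psma5 0.68 and Psmd9 0.52) were higher, each with a camera adjusted p of 0.0168. With an estimated correlation their adjusted p was 0.477, 0.477 and 0.394. Endothelial markers were lower (1 of 6 fallen, 2 over the list alone, Flt1 -0.85, camera adjusted p = 0.0168, and adjusted p = 0.135 with an estimated correlation). In all, 143 probes rose and 274 fell. Scaling to a common median moved the median of all probes from 0.03 to 0.15 and called 390 rises and 212 falls (64.8% higher, against 34.3% here). With the array set as a block 2158 probes passed, among them 226 of the 417. That fit set depletion against deficient 6 alone, an outlying sample of the same array set. It therefore cannot separate diet from what sets deficient 6 apart. Of the 5 lists only fatty acid synthesis passed with the block (median 0.75, camera adjusted p = 0.0216). The clock, cholesterol, proteasome and endothelial lists had medians of -1.60, -0.19, 0.03 and -0.56 (camera adjusted p = 0.447, 0.818, 0.821 and 0.544), and the cholesterol median and Psmd9 (-0.03) changed sign. Of the 17 genes named here 14 kept their call with the block, among them Dbp (-3.79), Bmal1 (2.17), Usp2 (-2.50), Hacl1 (-2.10), Insig2 (1.53) and Fdps (0.79), again against deficient 6 alone.

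The repletion effect differed from the depletion effect at 704 probes, 311 higher and 393 lower. Cholesterol synthesis genes differed (3 of 15 higher, 4 when adjusted over the list alone, median 0.61, camera adjusted p = 0.00237, and adjusted p = 0.385 with an estimated correlation), with Lss, Mvd and Fdps at 1.45, 1.04 and 0.63. Ribosomal protein genes differed (4 of 23 higher, 4 when adjusted over the list alone, median 0.42, camera adjusted p = 0.0021, and adjusted p = 0.64 with an estimated correlation), with Rplp1, Rps18 and Rpl21 at 0.79, 0.67 and 0.66, but with the array set as a block their median was -0.13. The block gave 141 probes, 57 higher and 84 lower and 8 of them among the 704, and none of the 6 genes named here. Lss, Mvd and Fdps were at 2.38, 1.88 and 0.58 and the cholesterol list passed (median 1.11, camera adjusted p = 0.017). Under the block depletion was tied to the other sets only through deficient 6, an outlying sample, and repletion only through chow and supplemented 1. The blocked values therefore do not strengthen the difference. Without the block it correlated across probes at 0.55 with the difference between chow samples of array sets 5 and 1, so array set is a candidate cause. Here scaling to a common median moved the median of all probes from -0.04 to -0.14 and gave 295 higher and 707 lower (29.4% higher, against 44.2% here).

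Of the probes called both between deficient and supplemented rats and between repletion and deficient rats, 139 in number, all changed in opposite directions, 76 up and then down and 63 down and then up. The deficient samples enter both comparisons with opposite sign, so opposite directions also arise without any change. The log2 differences correlated across probes at -0.634, against -0.426 in simulated unchanged groups that share the deficient samples and have no array sets, and the covariance was -0.1051 against -0.0164. With the deficient samples split between the comparisons the correlation was -0.392 and the covariance -0.0763. Most deficient samples lie in the same array set, so the split does not remove what array set adds to both comparisons. With the difference between chow samples of array sets 5 and 1, deficient against supplemented correlated at -0.184 and repletion against deficient at 0.609. The split value therefore cannot tell a reversal by PQQ from array set. Deficiency and depletion, both against supplemented rats, correlated at 0.271 against 0.451 simulated (covariance 0.0244 against 0.0197), 0.097 with the supplemented samples split (covariance 0.0097), and shared 1 called probe. Repletion against deficient and depletion against supplemented rats share no group, and their log2 differences correlated at 0.094 against 0.001 simulated. Of the 10 probes called after depletion, 6 were also called after repletion, all in the same direction. These were 1 higher and 5 lower in both, against 0.6 and 1.2 expected from independent lists. Giving and withdrawing PQQ therefore did not go with opposite changes at these probes. Genes are not independent replicates in these correlations.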

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

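All tests in this part were chosen after the results were seen, except the interaction between repletion and depletion.

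Within groups of 4 to 6 samples, 216 sets of values were examined for a sample far from the others of its group, and 22 were found, where chance gives about 10.8. Deficient 6 stood apart at Araf (8.63), Cyp51 (10.09), Mgll (10.23), Psma5 (10.85), Psmd9 (9.82), Rps20 (12.82), Scaf11 (8.2) and Tfam (9.85), all log2 values, and its mean correlation with its group was 0.85. Other deficient samples stood apart at Cdkn1a (deficient 4, 7.19), Rpl21 (deficient 2, 12.75) and Syt11 (deficient 1, 11.45). Supplemented 1 stood apart at Gne (9.75) and Marveld1 (9.63) and in its mean correlation with its group (0.96). Supplemented 2 did so at Atad2 (8.38) and Tsku (9.78), and supplemented 5 at Flt1 (9.35). Among repletion samples these were Acly (repletion 2, 13.87), Cry2 (repletion 3, 9.54), Cyp1a2 (repletion 1, 13.56) and Lman1 (repletion 4, 10.74).

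The repletion effect differed from the depletion effect at 704 probes by a test of the difference itself. Across probes it correlated at 0.55 with the difference between chow samples of array sets 5 and 1. The sign was the same in both for 90.5% of the called probes, so array set is a candidate cause here too. Control spots of 4 bacterial genes, which belong to no comparison of genes, gave a signal that differed between array sets. Their median intensities in array set 5 were 384.3 (FIXB), 431.4 (HISB), 195.2 (LEUB) and 206.7 (GND), against set medians of 4838 to 6924, 18400 to 21040, 7486 to 9350 and 757.7 to 4838 in sets 1 to 4. The highest GND median belonged to set 4. In set 5 HISB was low in chow arrays (352.7 to 491.1) and in repletion arrays (401.2 to 734.3). Chow arrays of set 1 had 19890 to 21180, and the order was the same for FIXB, LEUB and GND. For these spots, this argues against diet or injection as the cause of the low signal. All repletion samples lie in set 5, so their comparisons with deficient and supplemented rats also cross this difference between sets. What made set 5 differ was not tested.

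Other splits of the samples into groups of the same sizes were run to see whether chance could be excluded. The real split gave as many called probes as 1 of 100 splits, itself, for deficient against supplemented rats (179, highest other 164), repletion against deficient (1969, 859), chow against supplemented (517, 228), chow against deficient (1494, 754), repletion against supplemented (1038, 600), the interaction (704, 462) and repletion against chow (73, 29). For depletion against supplemented rats it was 1 of 56 (10, highest other 3). No other split drawn reached these counts, so chance is an unlikely source of them. It is not excluded, since at most 100 splits per comparison were drawn and samples of different array sets are not interchangeable. Nor do the splits separate diet from array set. For depletion against deficient rats, 2 of 84 splits gave as many, and the other, with 664 probes, set deficient 6, depletion 1 and depletion 2 apart, which all lie in array set 4. The blocked count there was 2158, but it set depletion against deficient 6 alone, a sample outlying in its group. It therefore cannot separate diet from what sets deficient 6 apart.

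Many probes differed between repletion and deficient rats, groups that lie in different array sets. The difference correlated at 0.609 across probes with the difference between chow samples of array sets 5 and 1, which share neither an array nor a diet with it, so array set is a candidate cause of a large part of it. An outlying deficient sample is argued against as the cause, because 2347 probes were called without the 2 outlying samples. Injected PQQ stays open, with 63 probes called under the array set block, 6 of them among the 1969, while 1449 of the 1969 kept their sign and the median SE rose from 0.151 to 0.31. Injection, PQQ and the link through chow and supplemented 1 cannot be told apart.

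Deficient 6, chow 6 and depletion 1 deviated from their groups alike, with Psmb4, Chpt1 and Clta among the genes lowest in all 3. Their deviations correlated at 0.693 (deficient 6 and chow 6, of different array sets) and 0.543 (deficient 6 and depletion 1), where the highest of 206 other pairs was 0.383. For chow 6 and depletion 1, array set and diet group are argued against by a correlation of 0.507 between their deviations from the other samples of their own group and set, where the highest of 74 reference pairs was 0.181, and for deficient 6 both stay open. A swapped or wrong group label is argued against by the clock index of deficient 6, which at 5 was the highest of the samples, since Dbp, Cry2, Nr1d2 and Bmal1 also passed without that sample. This covers deficient 6 only. The index may follow time of collection rather than diet, so it cannot show which diet that rat had. Chow 6 also had the highest index of its group (3.703), whereas depletion 1 (0.14) did not. RNA or hybridization quality may be the cause, since 3 of the 3 had the lowest share of probes above background of their group (83.6%, 85% and 85.4%). No biological explanation was tested.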

How the results depend on the processing

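Alternatives by array set, by counting each of 25 arrays, by leaving out 2 outlying arrays and all those of repletion against chow were chosen after seeing the data. Over all alternatives, counts moved by over 1.5 times 96 times and stayed within that 156 times. Named genes kept direction and side of the threshold 3839 times, weakened 491, strengthened 56 and reversed 38, and lists, by the direction camera gave, did so 469, 72, 1 and 1 times. The cause of a change was not tested except where fewer samples or another threshold make it by construction. Array signal limits the dim probes, and the scanner software's own normalized intensity and a block by slide or scan date were not run because the files give none.

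Depletion against supplemented rats moved most, from 10 probes to 20 with background subtracted without normexp, 252 with median scaling, 69 with the authors' table, 60 without a filter, 20 with a filter on all samples, 39 with defective spots kept (Ntrk3 reversed to 0.767), 1009 with array quality weights, 305 at unadjusted p under 0.01, 17 with a replicate block, 48 with array number as a covariate, 1513 and 0 with the array set as a fixed and a random block, where limma gave 796 at unadjusted p under 0.05 without a block, 86 with 25 arrays and 175 without the 2 outlying arrays. Without a filter repletion against deficient gave 3104, chow against deficient 2359 and depletion against deficient 841. Array quality weights gave 539 for deficient against supplemented, 890 for chow against supplemented, 2018 for repletion against supplemented, 1795 for depletion against deficient, 1812 for the interaction and 168 for repletion against chow. At unadjusted p under 0.01 deficient against supplemented gave 424 and repletion against chow 301. A change of at least 1.5-fold left 1039 for repletion against deficient, 281 for chow against supplemented, 657 for chow against deficient, 521 for repletion against supplemented and 268 for depletion against deficient. Fits of only the groups compared gave 34 for deficient against supplemented, 267 and 945 for chow against supplemented and deficient, 1684 for repletion against supplemented and 145 for depletion against deficient. Array number as a covariate gave 338 for deficient against supplemented, 504 for repletion against deficient, 88 for chow against supplemented, 13 for repletion against chow and 0 for repletion against supplemented (limma, 1797 at unadjusted p under 0.05 without the covariate).

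The array set as a fixed block gave 13 for deficient against supplemented, 63 for repletion against deficient, 121 and 91 for chow against supplemented and deficient, 71 for repletion against supplemented, 2158 for depletion against deficient and 141 for the interaction. As a random block it gave 100, 13, 60, 85, 5, 1440 and 1 in the same order, and 141 for repletion against chow. Within set 3 deficient against supplemented gave 9, within set 5 repletion against chow 33, within set 1 chow against supplemented 132 and within set 4 depletion against deficient 1022. Counting 25 arrays gave 836 for chow against supplemented and 166 for repletion against chow. Leaving out the 2 outlying arrays gave 288 for deficient against supplemented, 1645 for repletion against supplemented, 750 for depletion against deficient and 169 for repletion against chow.

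The fixed block reversed Syt11 (0.32), Hmgcs1 (-0.278), Cox4i1 (-0.238), Atp5f1d (-0.043) and Txnip (0.073) between repletion and deficient rats, Cox4i1 (-0.335) between repletion and supplemented, and the ribosomal protein list of the interaction (-0.125). Medians also turned negative, with the camera direction kept and the call lost, for oxidative phosphorylation after repletion (-0.044 against deficient, -0.038 against supplemented) and cholesterol synthesis between depletion and deficient rats (-0.188). Acsl3 between chow and supplemented rats (0.012) and Psmd9 between depletion and deficient (-0.026) reversed with the block and within sets 1 and 4. Genes that had not passed also changed sign. Stat3 after repletion turned to 0.015 with median scaling, 0.279 with array number, 0.405 and 0.262 with the fixed and random block, and 0.001, 0.015 and 0.046 without deficient 2, deficient 5 and repletion 3 (lowest when leaving out 1 sample -0.091). Tfam in deficient against supplemented rats turned to 0.037 with weights, 0.018 with array number, without deficient 6 and without the 2 outlying arrays, 0.004 without supplemented 1 (lowest -0.13, without supplemented 5), and 0.11 with the block and within set 3. Tfam after repletion turned to 0.027 with array number. Tfam after depletion turned to 0.182 with median scaling, 0.026 with the authors' table, 0.101 with weights, 0.125 with array number, 0.055, 0.007 and 0.137 without supplemented 1, supplemented 4 and depletion 3 (lowest -0.09, without depletion 1), 0.573 and 0.263 with the fixed and random block and 0.031 with 25 arrays. Txn1 after depletion turned to -0.097 with array number and -0.013 without supplemented 5 (highest 0.086).

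Of the lists called in other comparisons, those that lost the call when 1 sample was left out were cholesterol synthesis after repletion against deficient (largest adjusted p 0.0899, without repletion 3) and, between depletion and deficient rats, fatty acid synthesis (0.148) and endothelium (0.0565) without deficient 6, proteasome (0.0645) without depletion 2 and cholesterol synthesis (0.0743) without depletion 3.

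Leaving out 1 sample gave 82 (supplemented 1) to 268 (deficient 6) probes for deficient against supplemented, also 93, 98, 103, 115 and 115 without supplemented 3, deficient 2, supplemented 4, supplemented 2 and deficient 1. The range was 1583 to 2220 for repletion against deficient and 1073 to 1955 for chow against deficient. It was 2 (supplemented 4, depletion 2) to 25 (depletion 3) for depletion against supplemented, with 5, 6, 16 and 18 without supplemented 3, depletion 1, supplemented 5 and supplemented 2. Chow against supplemented gave 209 (chow 6) to 916 (chow 3), with 259, 262, 306 and 331 without chow 5, chow 4, supplemented 4 and supplemented 3. Repletion against supplemented gave 661 (repletion 3) to 1037, with 663 without repletion 1. Depletion against deficient gave 152 (depletion 2) to 650 (deficient 6), with 240 without depletion 3. The interaction gave 292 (depletion 1) to 899, with 439 without depletion 2. Repletion against chow gave 22 (chow 1) to 104, with 28, 28, 30 and 41 without repletion 1, repletion 2, chow 3 and repletion 3.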

Other observations

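The tests of this part, including the comparison of repletion with chow rats, were chosen only after the results were seen.

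The repletion samples share array set 5 with chow 4 to 6, while the other chow samples lie in set 1. Between chow samples of sets 5 and 1, 459 probes differed. Genes that differed between repletion and chow rats included some of lipid and drug metabolism. Serpina7, a thyroxine carrier, was 4.25-fold higher after repletion (log2 difference 2.09, SE 0.37, 4 repletion and 5 chow samples, adjusted p = 0.00617), and A2m, a protease inhibitor (1.77), Nupr1, a stress response gene (1.42), and Fabp2 (1.27) were higher too. Cyp2c22 and Cyp3a9, cytochrome P450 enzymes, fell by 2.10 and 1.65, Sds by 2.08, Fmo5 by 1.32, Hacl1 by 1.23 and Gdf15 by 1.21. Fatty acid synthesis genes were higher (1 of 16 risen, 6 when adjusted over the list alone, median 0.49, camera adjusted p = 1.92e-06, and adjusted p = 0.0752 with an estimated correlation), with Fads2 at 0.96, while Acly (1.28), Fasn (1.23) and Elovl6 (1.17) did not pass. Cholesterol synthesis genes were higher (1 of 15 risen, 4 over the list alone, median 0.41, camera adjusted p = 0.000105, and adjusted p = 0.0812 with an estimated correlation), with Fdps at 0.89. Xenobiotic metabolism genes were lower (4 of 32 fallen, 8 over the list alone, median -0.36, camera adjusted p = 0.000408, and adjusted p = 0.0752 with an estimated correlation), among them Cyp1a2 (-0.88). In all, 31 probes rose and 42 fell. Within set 5, with 4 repletion and 3 chow samples, 33 passed and 73 of the 73 kept their sign. These samples also enter the main fit, so the kept signs are not separate evidence. The block for array set gave 107 probes, 48 of them among the 73, and 14 of the 18 called genes named here, with Serpina7 at 2.14, A2m at 1.92, Cyp2c22 at -1.98 and Sds at -2.16, while Cdo1, Ddc, Cd14 and Rps18 did not pass and Acly (1.53) and Fasn (1.43) did. It kept 8 of the 9 lists, all but oxidative phosphorylation. Scaling to a common median gave 37 higher and 29 lower (56.1% higher, against 42.5% otherwise).

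Further lists passed between these groups by camera, and none did with an estimated correlation. Ribosomal protein genes (median 0.25, camera adjusted p = 2.74e-06, estimated 0.198, Rps18 0.59), the acute phase response (0.15, 0.0103, estimated 0.198, Cebpd 1.02), immediate early genes (0.15, 0.0127, estimated 0.0752) and oxidative phosphorylation (0.16, 0.0446, estimated 0.411) were higher. Amino acid and urea metabolism (-0.16, 0.0103, estimated 0.215, Cdo1 -0.69 and Ddc -0.66) and Kupffer cell markers (-0.27, 0.0265, estimated 0.247, Cd14 -0.74) were lower. Leaving out 1 sample kept 4 of the 9 lists in every fit. Oxidative phosphorylation lost its call in 5 such fits (adjusted p up to 0.203, without chow 3), Kupffer cell markers in 5 (up to 0.107, without chow 6), the acute phase response without chow 6 (0.0511), and immediate early genes (0.0957) and amino acid metabolism (0.0552) without repletion 4. The immediate early median ranged from 0.082 (without chow 4) to 0.38 (without chow 6). Diet base, injection and PQQ differ together between these groups.

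Clock genes differed between deficient and supplemented rats. For Dbp and Bmal1 array set as the whole cause is argued against by their differences within set 3, 1.965 and -1.299 (adjusted p = 0.00627 and 0.047 over all probes), and for the other clock genes it stays open. An index, the mean of Dbp, Nr1d2, Cry2 and Usp2 minus Bmal1, was 4.57 in deficient, 2.8 in chow, 1.83 in supplemented, 1.72 in repletion and 0.46 in depletion samples, with genes and signs chosen from the difference between deficient and supplemented rats, so that difference is not tested with it. The amount of PQQ in the diet stays open, since depletion samples lay below supplemented ones by -1.37 but share no array set with them. Different times of day of collection may be a cause, because Dbp and Bmal1 varied in opposite directions within groups (r = -0.76, permutation p = 0.00044, 23 samples), but without recorded times this cannot be told apart from a diet effect.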
